A study of Mus musculus with 6 samples.

How the data were processed

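Gene expression was measured in whole liver of 6 mice on a high-fat diet for 2 weeks, 3 wild-type B6 mice (WT) and 3 mice carrying a LIGHT transgene (LIGHT Tg). The groups follow the titles and source names; the free-text descriptions call all 6 samples wild-type, so they disagree with the other labels for the 3 LIGHT Tg samples, and every comparison rests on the titles and source names. The source names give B6 for the WT mice only and name no strain for the LIGHT Tg mice. A difference in genetic background therefore cannot be told apart from the transgene in any comparison here. LIGHT is the tumour necrosis factor family ligand encoded by Tnfsf14. Per the labels, the mice were 4 to 8 weeks old, and biotin-labelled cRNA made from total RNA was hybridised to 1 Affymetrix array per sample. The sample titles number the samples; nothing in the labels used here says outright that each is a separate animal, and p-values measure the spread between these 6 samples. Replicate numbers were given in listing order and pair no samples. The title numbers are 78, 30 and 31 for WT 1 to 3 and 77, 34 and 35 for LIGHT Tg 1 to 3, so each genotype has 1 array titled 77 or 78 and 2 arrays titled 30 to 35. What the number means is not given in the sources used here.

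The values are the authors' MAS5 intensities, 1 signal per probe set on a linear scale, as deposited. MAS5 is named in the submitters' processing notes, and its version, scaling target and detection calls are not given in the sources used here. The trimmed mean signal, leaving out 2 percent at each end, lay between 490.0 and 505.1 on the 6 arrays, so scaling per array to a common target is read from the values. Median signals lay between 175.1 and 183.1. Without detection calls no probe set could be called absent, and low signals carry no bound. The number of arrays limits the precision.

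The table held 45101 probe sets, of which 64 control probe sets were left out of all tests. Genes were named from the annotation table of the array, checked against RefSeq gene names of the assembly GRCm38.p6, which changed 0 symbols. Of the other 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. No gene was named from a probe set with several symbols. No coordinates are given because no genome build was named for the array.

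Signals below 1 (106 values) were set to 1 and log2 was taken. Probe sets were tested where the mean log2 signal over the 6 arrays was at or above the median of 7.387, a signal of 167.4, which left 22519. LIGHT Tg was compared with WT in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a variance trend, without further normalization between arrays, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 5% FDR. Fold changes are LIGHT Tg minus WT on the log2 scale with the moderated standard error. As the title numbers form sets that both hold each genotype, the fit was repeated with that set as a block, and list medians within each set are given. Exact permutation of 3 against 3 arrays cannot give a p below 0.1.

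Gene lists were fixed before the data were examined, 29 in all, and 24 had at least 5 members past the filter. Each was tested with camera at its preset correlation of 0.01, with 1 probe set per gene (the one with the highest mean), which refits the same model on 11563 genes. camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run beside it. Of 557 list entries, 65 were not matched to a probe set and were not analysed here.

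The genes to be named were also fixed before the data were examined. They are Tnfsf14 and its receptors Ltbr and Tnfrsf14; the 15 genes with the largest rise and the 15 with the largest fall past 5% FDR whose groups do not overlap; up to 4 members with the largest moderated statistic from each list described; and 2 members with the highest level from each cell type list. After the data were seen, 4 members were named from lists past the threshold and 2 from other lists, which leaves 33 of the 141 genes that the rule takes from tested probe sets out of the paragraphs on lists. Genes named outside this rule are said to be so. 1 further gene of the rule is not reported here.

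The alternatives were no filter, a filter at the 75th percentile, an offset of 37.4 (the 20th percentile of all values) before log2, quantile normalization, arrays shifted to a common median, eBayes without the trend or with robust fitting (for lists, camera on the robust statistics), array weights, the title-number block, each array left out in turn, and for genes the mean of all probe sets. Use of the arrays titled 30 to 35 alone was added after seeing the data. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

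The steps were tested on simulated data for this comparison, with 22519 probe sets at the real levels, residual spread and title-set differences, 20 simulations and 200 changed probe sets. The fit without the block recovered 9.3% of 2-fold, 59.3% of 4-fold, 82.8% of 8-fold and 90.0% of 16-fold changes, with 0.9 false calls on average. The block fit recovered 39.2%, 82.6%, 93.9% and 96.5%, with 6.3 false calls on average. With no probe set changed, neither fit made a call. A list lowered by 0.5 log2 was found in 20 of 20 simulations. Of the lists called in the real data only the male-biased one had a larger median shift (-0.687). Smaller shifts were not simulated. With no list shifted, camera at the preset correlation on 11563 genes called at least 1 of the 24 lists in 21 of 100 simulations, which is more than the nominal rate. The simulated noise was independent between genes. In the real data the estimated correlation was 0.12 in the bile acid list, the one lowered here, and 0.626 in the female-biased list. The simulated list rates may therefore not hold for the real lists, where false calls may be more frequent.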

Results

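Liver RNA of 3 WT and 3 LIGHT Tg mice was profiled on 6 arrays after 2 weeks of high-fat diet, to compare hepatic expression between the genotypes. The genotypes are those of the titles and source names, while the description of each LIGHT Tg sample speaks of wild-type mice. Signals summed to between 30980000 and 32710000 per array. Correlations between arrays across probe sets lay between 0.847 and 0.974. The first principal component, with 48.0% of the variance, parted the arrays titled 77 and 78 (WT 1 and LIGHT Tg 1) from the 4 arrays titled 30 to 35, and the next, with 30.3%, parted the genotypes.

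The arrays titled 77 and 78 differed from the others in control and sex-linked signals. At the 5' probe set for the 18S ribosomal RNA control the signal was 243.4 and 196.4 on WT 1 and LIGHT Tg 1, and between 17440 and 17950 on the other 4. The gap was smaller at the 3' probe set, with 244.1 and 437.2 against 3548 to 5475. Xist, the transcript of the inactive X chromosome, was lower on that pair at each of its 3 probe sets, with signals of 444.0 and 406.6 against 7993 to 9714, 7.1 and 5.4 against 6673 to 8406, and 5.23 and 28.6 against 1071 to 1465. The Y-linked gene Eif2s3y had signals of 1037 and 1272 on the pair and at most 2.82 elsewhere, and at a dimmer probe set 62.6 and 41.5 against 4.4 to 29.6. Kdm5d and Uty, also Y-linked, are named outside the rule. Uty was higher on the pair at each probe set, with 435.8 and 245.6 against 76.2 to 132.3 at the brightest. Kdm5d had 568.6 and 487.8 against 41.28 to 108.3 at its brightest probe set. Its other probe sets overlapped, with 44.92 and 111 against 15.94 to 108.1, and 57.92 and 121.5 against 8.55 to 105.1. The Xist, Eif2s3y and Uty signals show a male pattern in the pair and a female pattern in the other 4 arrays. In the fit with genotype and title-number set, 6163 of 22519 probe sets differed between the sets at 5% FDR. Each genotype has 1 array of the pair, so the count of probe sets and the gene lists are given with the block too, and the lists also with their medians in the pair and in the arrays titled 30 to 35 (the others).

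**Figure D1:**
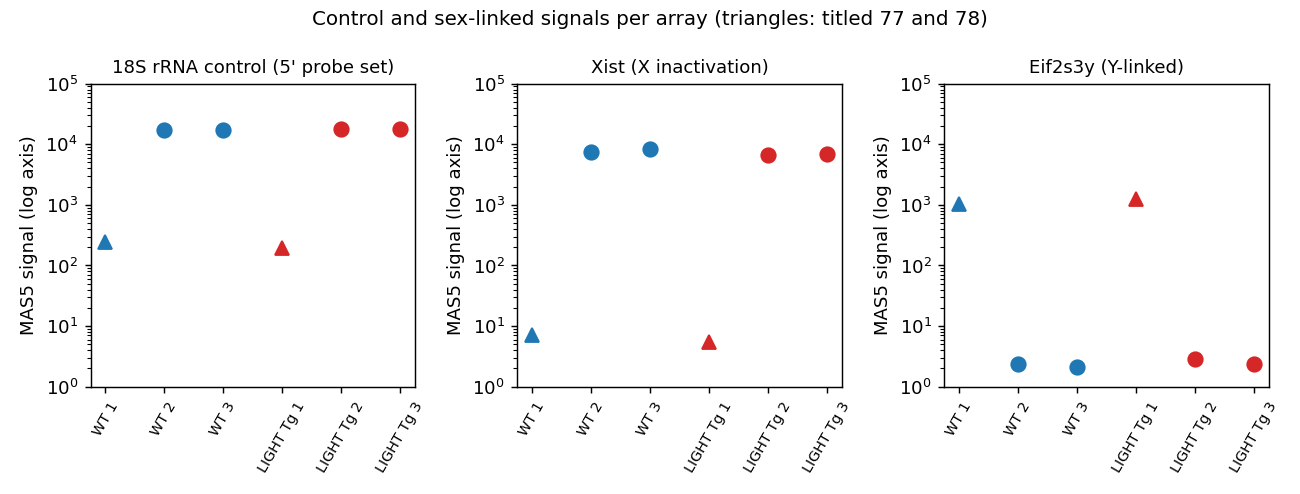
MAS5 signal on a log axis of the 18S ribosomal RNA control (5' probe set), Xist (1 of its 3 probe sets) and Eif2s3y (1 of 2; 1 point per array, WT in blue, LIGHT Tg in red). The triangles, WT 1 and LIGHT Tg 1, had 5' 18S signals of 243.4 and 196.4 against 17440 to 17950 on the other 4 arrays.

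The transgene was checked first. Of 2 probe sets for Tnfsf14, the brighter had signals of 55.7, 19.3 and 26.7 in LIGHT Tg 1 to 3 and of 7.7, 11.9 and 7.43 in WT 1 to 3, a log2 difference of 1.80 ± 0.594 (SE, n = 3 per group). All LIGHT Tg values lay above all WT values. Its level was at the 8.88th percentile of all probe sets, and the difference did not pass the limma test (adjusted p = 0.423 over all non-control probe sets, 0.176 with the block). With the offset before log2 it was 0.59. The other probe set had a difference of -0.55 ± 0.543. Whether the probes lie in the transgene's transcript is not given in the sources used here, so these values neither check nor contradict the labels. The receptor Ltbr had a log2 difference of -0.36 ± 0.344 (adjusted p = 0.833), and Tnfrsf14, also at low signal, 0.66 ± 0.542 (adjusted p = 0.908).

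LIGHT Tg livers had large differences in genes of varied function. Gpx3, a secreted glutathione peroxidase, rose by 4.12 ± 0.262 on the log2 scale (17.5-fold, SE, n = 3 per group), the tetraspanin Cd9 by 2.96 ± 0.172, the imprinted gene Peg3 by 4.02 ± 0.341 and Prom1, a membrane glycoprotein of bile duct and progenitor cells, by 4.20 ± 0.483. Aox3, an aldehyde oxidase, fell by 5.02 ± 0.710, Ddah1, which degrades asymmetric dimethylarginine, fell by 3.93 ± 0.246, and the P450 gene Cyp2c50 fell by 3.02 ± 0.248. The complement genes C8a and C9 had log2 changes of -2.73 ± 0.448 and -2.50 ± 0.390. All of these passed 5% FDR in the limma fit, with all 3 LIGHT Tg values on one side of the 3 WT values, as the rule for naming them requires.

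In all, 264 of 22519 probe sets passed 5% FDR, 161 higher and 103 lower in LIGHT Tg, and 2473 had an unadjusted p below 0.05. These 264 hold 191 different genes among 241 probe sets with 1 symbol, and 242 changed at least 2-fold. With the title-number block 1457 passed (734 higher, 723 lower), all 264 among them. In the arrays titled 30 to 35 alone 956 passed, an alternative chosen after seeing the data. Leaving out 1 array gave 306 without WT 1, 68 without WT 2, 63 without WT 3, 214 without LIGHT Tg 1, 80 without LIGHT Tg 2 and 43 without LIGHT Tg 3. These fits had no block, and leaving out 1 array makes the title-number sets unequal between the genotypes. Of the named genes past the threshold, 15 of 46 stayed past it whichever array was left out: Gpx3, Crybb3, Peg3, Sdr16c5, Ighm, Marveld3, Cd9, Ddah1, Ildr2, Enpp3, Cyp2c50, Etnppl, Il1rap, Gas2 and Khk. The other 31, among them Prom1, Aox3, C8a and C9, lost the call without at least 1 array. With the block 23 more of the named genes passed (adjusted p between 0.00403 and 0.0498); apart from Id3, Car3 and Cela1 they are marked in the paragraphs on lists.

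Among the 15 genes with the largest rises, Ccdc38 rose by 5.58 ± 0.504 on the log2 scale. The nicotinic receptor subunit gene Chrna2 rose by 4.35 ± 0.528, with 2.55 in the pair and 5.24 in the arrays titled 30 to 35. The crystallin Crybb3 rose by 4.12 ± 0.248, the axonemal dynein Dnah11 by 3.90 ± 0.382, Bpifa1 by 3.86 ± 0.491 and Sdr16c5 by 3.73 ± 0.319. The immunoglobulin heavy chain gene Ighm rose by 3.62 ± 0.208 at 1 probe set. Of its 6 tested probe sets another rose by 4.84 and the other 4 lay between -0.39 and 0.52, so the value holds for part of the locus, and these probe sets can share sequence with other immunoglobulin genes. 2210407C18Rik rose by 3.40 ± 0.356, Sult4a1 by 3.33 ± 0.534, the integrin subunit Itga6 by 3.11 ± 0.308 and Marveld3 by 2.98 ± 0.198, while its other tested probe set had 1.51 (adjusted p = 0.122). Adjusted p for these 11 genes lay between 0.000821 and 0.0393. The WT means of Ccdc38, Dnah11, Chrna2, Bpifa1, Sult4a1, Sdr16c5, Marveld3, Prom1 and Crybb3 lay between 4.90 and 7.33, below the filter level of 7.387. These genes were tested because their LIGHT Tg signals were high, and the size of their rises is less certain. Over the alternative settings the rise was as low as 4.425 for Ccdc38 and 3.516 for Chrna2.

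Among the 15 with the largest falls, Ildr2 fell by 3.09 ± 0.167 and the ectonucleotidase Enpp3 fell by 3.06 ± 0.243. Paqr7 fell by 3.02 ± 0.313 and the major urinary protein gene Mup10 fell by 2.80 ± 0.476. Etnppl fell by 2.73 ± 0.225, the lipid droplet gene Plin4 fell by 2.69 ± 0.440 and Il1rap, an accessory protein of the interleukin-1 receptor, fell by 2.68 ± 0.178. Retinol saturase, Retsat, fell by 2.46 ± 0.290, Gas2 fell by 2.43 ± 0.209 and the natriuretic peptide receptor Npr2 fell by 2.37 ± 0.287. Adjusted p for these 10 genes lay between 0.000821 and 0.0472. Of 3 other probe sets of Enpp3, 2 fell, by 4.22 and by 2.43, and 1 had -0.13. Another probe set of Gas2 had -0.17, and 3 others of Il1rap lay between -0.63 and -0.29. The other of Ildr2 had -2.64 (adjusted p = 0.169), and of 4 others of Ddah1, 3 fell and 1 had -1.73 (adjusted p = 0.606). Mup and Cyp2c genes have close paralogs that their probe sets may share, so the member that changed is uncertain.

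**Figure D2:**
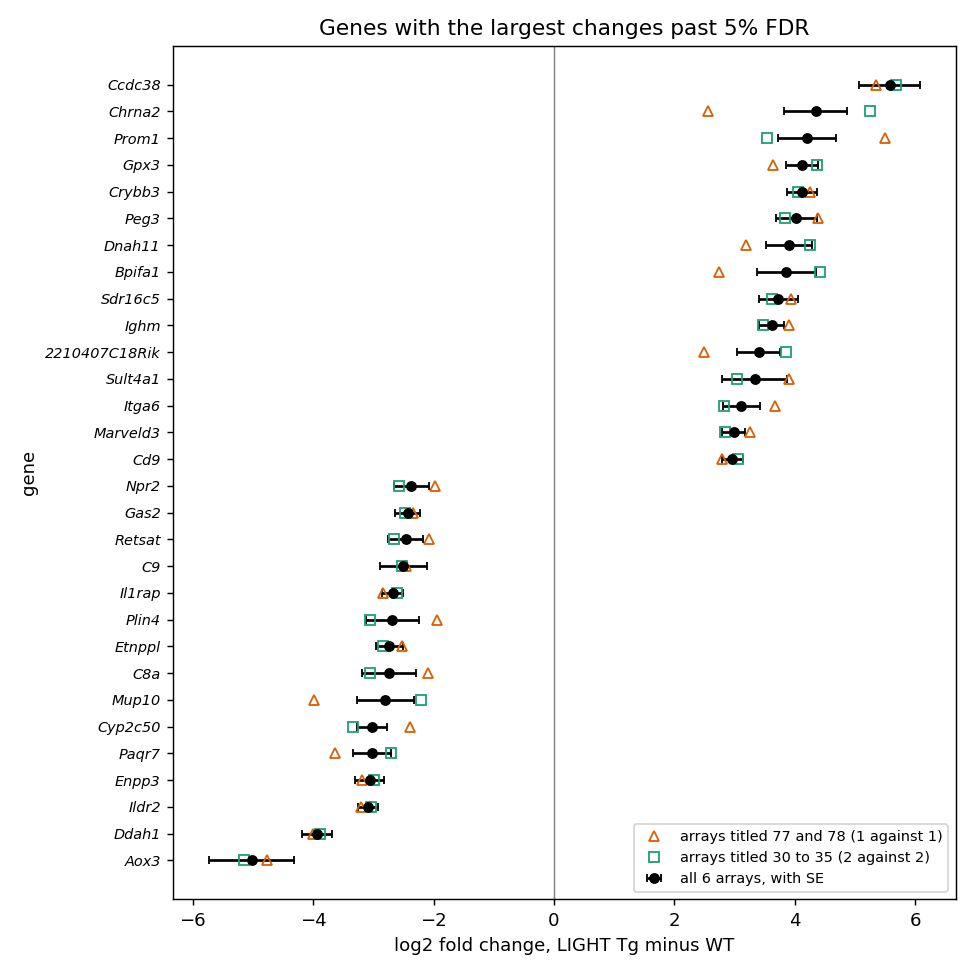
Log2 fold change, LIGHT Tg minus WT, of the 15 genes with the largest rises and the 15 with the largest falls past 5% FDR. Black points are all 6 arrays with SE, triangles the pair titled 77 and 78 and squares the arrays titled 30 to 35. Only genes whose groups do not overlap were taken, which gives the 3 values of a gene the same sign.

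Genes of bile acid synthesis and transport were lower in LIGHT Tg. Of 23 measured, 3 fell and 20 did not pass, and 21 had negative log2 changes (median -0.35; -0.66 in the pair, -0.32 in the arrays titled 30 to 35). Adjusted over the list alone, 9 fell and 1 rose, and with the block 9 fell. The export pump gene Abcc3 fell by 1.72 ± 0.211 and the bile salt uptake transporter Slc10a1 fell by 1.25 ± 0.160. Nr1h4, the bile acid receptor, fell by 1.28 ± 0.206, and Slco1b2 had -1.03 ± 0.222 (adjusted p = 0.097, and 0.00403 with the block). Without LIGHT Tg 2 the median was -0.58. The camera test gave an adjusted p of 3.48e-07 (8.62e-07 with the block), and an adjusted p = 0.365 with an estimated correlation.

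Glucose metabolism genes were lower by the same test. Of 18, 2 fell and 16 did not pass (median -0.25; -0.31 in the pair, -0.26 in the others). Of these genes 3 fell adjusted over the list alone, and 3 with the block. Khk, ketohexokinase, fell by 1.47 ± 0.118 and the glucose transporter Slc2a2 fell by 1.57 ± 0.262. Pygl, which passed with the block, had -0.51 ± 0.130 and Ppp1r3c -0.67 ± 0.239. The camera adjusted p was 0.00487 (0.0182 with the block), 0.062 without LIGHT Tg 1, 0.0894 in the arrays titled 30 to 35, and adjusted p = 0.365 with an estimated correlation. Genes of xenobiotic metabolism were lower, with 1 of 22 fallen and 21 not passed (median -0.33; -0.22 in the pair, -0.44 in the others). Both adjusted over the list alone and with the block 5 fell and 1 rose. Cyp2c38 fell by 2.20 ± 0.331, while Ces2a had -1.38 ± 0.314, Aldh1a1 -0.55 ± 0.121 and Gstm2 0.98 ± 0.230, all 3 of which passed with the block. Without LIGHT Tg 3 the median was -0.21. The camera adjusted p was 0.00379 (0.00443 with the block), and adjusted p = 0.619 with an estimated correlation.

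The unfolded protein response list was higher, with 1 of 17 risen and 16 not passed (median 0.22; 0.22 in the pair, 0.27 in the others). There were 2 that rose adjusted over the list alone, and 4 with the block. The median was 0.03 without WT 1, 0.13 without LIGHT Tg 3 and 0.39 without LIGHT Tg 1. The transcription factor Atf4 rose by 0.96 ± 0.163, Sdf2l1 had 0.998 ± 0.209 and Creld2 1.06 ± 0.304, which passed with the block, and Dnajb9 had 0.42 ± 0.195. The camera adjusted p was 0.00517 (0.000563 with the block), 0.108 without WT 1, 0.0523 without LIGHT Tg 2, and adjusted p = 0.619 with an estimated correlation. Endothelial markers were higher, with 2 of 14 risen and 12 not passed (median 0.18; 0.10 in the pair, 0.28 in the others, 0.32 without WT 1). Both adjusted over the list alone and with the block 3 rose. Von Willebrand factor, Vwf, rose by 2.39 ± 0.229 and the lymphatic and sinusoidal receptor Lyve1 by 1.24 ± 0.200. Stab2, which passed with the block, had 0.75 ± 0.176, Clec4g 0.36 ± 0.175 and Mrc1 0.07 ± 0.179. The camera adjusted p was 0.00487 (0.013 with the block), and adjusted p = 0.463 with an estimated correlation.

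Male-biased liver genes were lower in the fit over 6 arrays. None of 9 passed singly, 1 fell adjusted over the list alone and 2 fell with the block, Elovl3 and Cyp2d9. The median was -0.69, with -3.16 in the pair and -0.13 in the others; it was -1.54 without WT 2, -1.07 without LIGHT Tg 2, -1.28 with the stricter filter, -1.10 with none and -0.19 with array weights. Elovl3 had -2.61 ± 0.553, Serpina4-ps1 -1.88 ± 0.613, Ugt2b38 -1.51 ± 0.696 and Cyp2d9 -2.13 ± 1.05, and in the arrays titled 30 to 35 alone these genes had -1.85, -1.08, -0.48 and -1.62. The camera adjusted p was 0.0213 (0.0183 with the block), 0.261 without WT 1, 0.0558 without LIGHT Tg 1, 0.200 in the arrays titled 30 to 35, 0.209 with array weights, and adjusted p = 0.695 with an estimated correlation. The 13 female-biased genes had a median of 0.82, with 2.45 in the pair and -0.26 in the others (adjusted p = 0.144, and 0.167 with the block). None passed singly and 4 rose with the block, among them Cyp3a44 at 4.02 ± 1.13, with 6.91 in the pair and 2.57 in the others, and Cyp3a16 at 5.42 ± 1.67, with 8.91 and 3.67. The list passed, higher, without WT 2 (median 1.31, adjusted p = 0.0102) and without WT 3 (median 0.98, adjusted p = 0.0106). These fits had no block. In them WT 1, with a mean of 7.06 over this list, weighed more in WT than LIGHT Tg 1 did in LIGHT Tg. The passes may come from that imbalance. Of the 13, 8 had positive and 5 negative log2 changes. Cyp2b13 at -2.84 ± 1.35 and Cyp2b9 at -2.76 ± 1.48 were chosen after their values were seen, with 0.11 and 0.52 in the pair and -4.31 and -4.40 in the others (adjusted p = 0.00328 and 0.00348 in these 4 arrays alone).

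**Figure D3:**
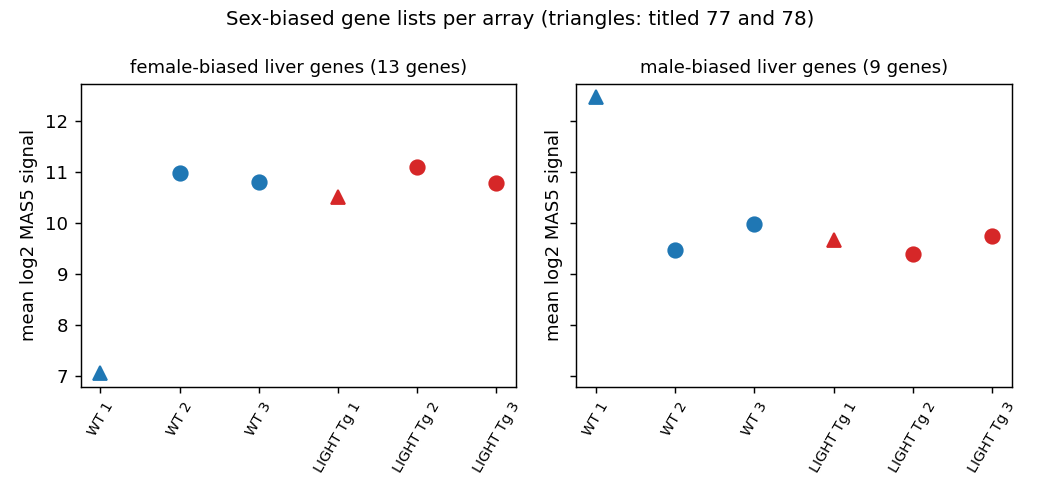
Mean log2 MAS5 signal of the female-biased (13 genes) and male-biased (9 genes) lists in each array, WT in blue and LIGHT Tg in red, triangles for the arrays titled 77 and 78. WT 1 stands at 7.06 and 12.5, and the other 5 arrays between 10.5 and 11.1 and between 9.38 and 9.97.

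**Figure D4:**
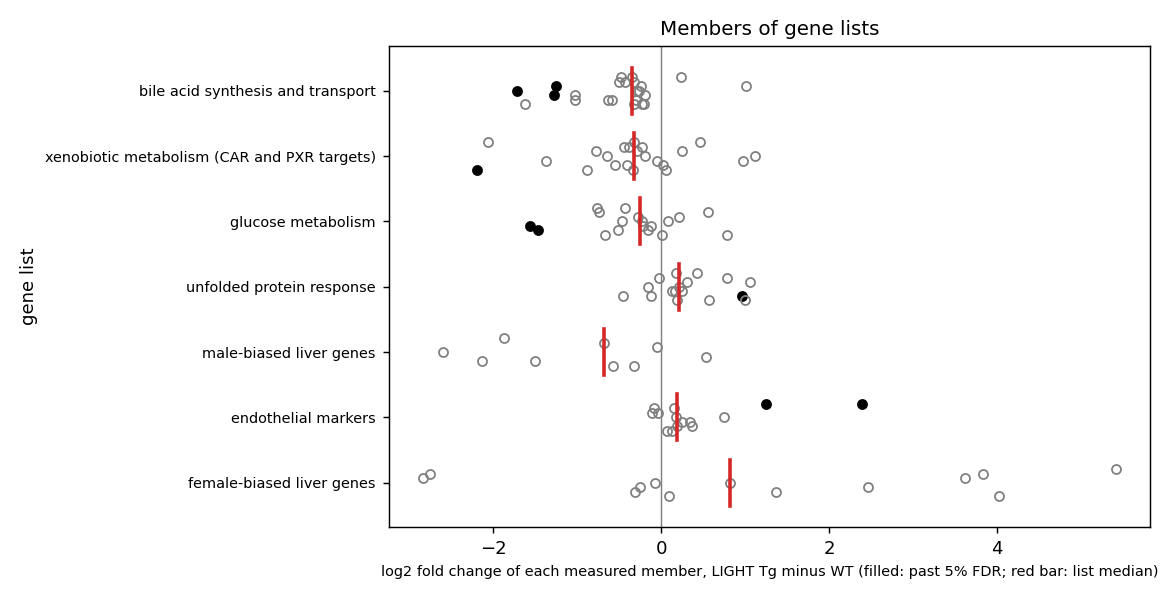
Log2 fold change, LIGHT Tg minus WT, of each measured member of the 6 lists past 5% FDR with camera and of the female-biased list. Filled points passed 5% FDR singly and red bars are list medians, from -0.69 for male-biased to 0.82 for female-biased genes.

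At the preset correlation 6 of the 24 lists passed. In simulations of this comparison with no list shifted and with genes varying independently, at least 1 list was called in 21 of 100. None of the 24 lists passed with an estimated correlation, where 2 had an unadjusted p below 0.05, and fry passed 2, glucose metabolism and the B cell and plasma cell list. The mixed form of fry, which counts changes in either direction, also passed the fatty acid and triglyceride synthesis list (adjusted p = 0.000292) and the PPARalpha list (0.00396). It passed the bile acid, xenobiotic, glucose, endothelial and B cell lists as well, and shows no common direction.

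Lipid gene lists did not pass with camera over the 6 arrays. Of 22 fatty acid and triglyceride synthesis genes, 2 rose, Fads2 by 0.72 ± 0.114 and Acacb by 1.16 ± 0.194 (median -0.07; -0.10 in the pair, -0.19 in the others; adjusted p = 0.363, and 0.460 with the block). Both adjusted over the list alone and with the block 4 rose and 5 fell. None of 20 cholesterol synthesis genes passed (median 0.31; 0.66 in the pair, 0.13 in the others; adjusted p = 0.122, and 0.167 with the block), with Mvd at 1.86 ± 0.379 and Fdps at 0.90 ± 0.319. Adjusted over the list alone 1 rose, and with the block Mvd rose. The list passed without WT 2 (median 0.46, adjusted p = 0.0434), without WT 3 (0.44, 0.00434) and without LIGHT Tg 2 (0.44, 0.0314). None of 27 lipase, apolipoprotein and lipoprotein genes passed (median 0.01; -0.05 in the pair, 0.02 in the others; adjusted p = 0.512, and 0.525 with the block), with Lipg at -1.33 ± 0.368 and Apoc2 at 0.61 ± 0.197. With the block 2 rose, Apoc2 among them, and 1 fell. None of 27 PPARalpha targets passed (median -0.09; -0.21 in the pair, -0.04 in the others; adjusted p = 0.255, and 0.315 with the block), with Acaa1b at -1.03 ± 0.211 and Cyp4a14 at -4.23 ± 0.944. Adjusted over the list alone 1 rose and 4 fell, and with the block 4 rose and 4 fell, Acaa1b and Cyp4a14 among the latter. The PPARalpha list passed, lower, without LIGHT Tg 2 (median -0.19, adjusted p = 0.0306).

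Inflammatory, immune, cell cycle, immediate early and clock lists did not pass over the 6 arrays either. Of 27 acute phase genes the serum amyloid gene Saa4 fell by 0.95 ± 0.145 (median -0.12; -0.05 in the pair, -0.06 in the others; adjusted p = 0.237, and 0.167 with the block), and Socs3 had 0.85 ± 0.319; 1 fell adjusted over the list alone, and 2 with the block. This list passed, lower, without LIGHT Tg 1 (median -0.31, adjusted p = 0.0223). None passed among 18 genes of LIGHT, its receptors and NF-kappaB (median 0.10; -0.13 in the pair, 0.17 in the others; adjusted p = 0.363, and 0.525 with the block), with Rela at 0.36 ± 0.183 and Vcam1 at 0.31 ± 0.195. None passed among 25 interferon-stimulated genes (median -0.03; 0.19 in the pair, -0.11 in the others; adjusted p = 0.867, and 0.920 with the block), with Xaf1 at -0.74 ± 0.305 and Irf1 at -0.37 ± 0.162. None passed among 8 MHC class II genes (median -0.10; 0.18 in the pair, -0.27 in the others; adjusted p = 0.867, and 0.804 with the block), with Ifi30 at 0.56 ± 0.237 and H2-DMa at -0.39 ± 0.296. Cell cycle genes had a median of -0.09 and a mean of 0.19, so that median and test differ in sign (0.33 in the pair, -0.13 in the others; adjusted p = 0.842, and 0.920 with the block), with Ccna2 at 0.64 ± 0.198 and Pcna at -0.40 ± 0.141. Immediate early genes had a median of 0.15 (0.29 in the pair, 0.08 in the others; adjusted p = 0.363, and 0.525 with the block), with Egr1 at 1.496 ± 0.365 and Zfp36 at -1.04 ± 0.303, both past the threshold with the block. Clock genes had -0.29 (-0.23 in the pair, -0.40 in the others; adjusted p = 0.0982, and 0.167 with the block), with Hlf at -0.74 ± 0.218, past the threshold with the block, and Per1 at -0.56 ± 0.222. They passed as a list, lower, with no filter (median -0.35, adjusted p = 0.0493), with array weights (-0.53, 0.0367), without WT 2 (0.0449) and without LIGHT Tg 2 (0.0346).

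Markers of other cell types did not pass as lists with camera over the 6 arrays, apart from the endothelial one. With fry the B cell and plasma cell list passed (adjusted p = 0.0048) and the endothelial list did not (adjusted p = 0.0545). In the main fit Ighm had a moderated t of 17.4, against a mean of 3.34 for the B cell and plasma cell list. The other 5 markers had a median log2 change of 0.136, with 2 of them negative, so the result does not show that these markers rise together. Of 6 B cell and plasma cell markers Ighm rose (median 0.17; 0.15 in the pair, 0.13 in the others; adjusted p = 0.072, and 0.167 with the block; 1 rose adjusted over the list alone), and Jchain had 0.94 ± 0.332 and Cd22 0.20 ± 0.339. This list passed with camera on robust statistics (adjusted p = 6.5e-05), without WT 2 (median 0.29, adjusted p = 0.0449) and without LIGHT Tg 2 (median 0.26, adjusted p = 0.0368). With camera at an estimated correlation its adjusted p was 0.463. T and NK cell markers had a median of 0.12 (-0.06 in the pair, 0.21 in the others; adjusted p = 0.544, and 0.545 with the block), with Prf1 at 0.36 ± 0.273, Cd8a at 0.12 ± 0.168 and Zap70 at -0.05 ± 0.336. Kupffer cell, macrophage and dendritic cell markers had -0.06 (0.22 in the pair, -0.22 in the others; adjusted p = 0.548, and 0.626 with the block), with Clec4f at -0.36 ± 0.174, Marco at 1.20 ± 0.662, Csf1r at -0.08 ± 0.168 and Cd5l at -0.30 ± 0.225. Neutrophil markers had -0.05 (0.40 in the pair, -0.68 in the others; adjusted p = 0.544, and 0.676 with the block), with Mpo at -0.88 ± 0.401, Elane at -0.61 ± 0.309, S100a8 at -0.05 ± 0.768 and Ngp at -0.48 ± 0.422. Stellate cell and fibrosis markers had -0.07 (0.03 in the pair, -0.14 in the others; adjusted p = 0.332, and 0.393 with the block), with Ccn2 at -1.03 ± 0.295, which passed with the block, Lrat at -1.25 ± 0.436, Dcn at -0.01 ± 0.158 and Colec11 at 0.13 ± 0.217. Hepatocyte markers had -0.03 (-0.12 in the pair, -0.02 in the others; adjusted p = 0.363, and 0.197 with the block), with Cebpa at -0.28 ± 0.127, Otc at -0.42 ± 0.231, Apoa1 at -0.00023 and Ttr at -0.01.

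Lists with fewer than 5 members past the filter were tested without it. Bile duct and progenitor cell markers had a median of 0.14 (0.13 in the pair, 0.05 in the others; adjusted p = 0.514, and 0.571 with the block), with Epcam at -0.55 ± 1.21 against the rise of Prom1. Adipocyte markers had -0.15 (-0.11 in the pair, 0.01 in the others; adjusted p = 0.385, and 0.531 with the block), with Car3 at -1.73 ± 0.607 and Fabp4 at 0.20 ± 0.385. The WT mean of Car3 was 14.24, near the 14.28 of the hepatocyte marker Ttr, and that of Fabp4 was 9.99. The change of Car3 may therefore not be one of adipocytes. Pancreatic acinar markers had 0.03 (0.08 in the pair, 0.15 in the others; adjusted p = 0.642, and 0.824 with the block), with Cela1 at -0.59 ± 0.185 and Cela3b at 0.86 ± 0.238. Adjusted over the list alone 2 rose and 1 fell, and with the block 1 fell. Erythroid markers had -0.26 (-0.69 in the pair, 0.29 in the others; adjusted p = 0.353, and 0.446 with the block), with Alas2 at -0.57 ± 0.561 and Slc4a1 at 0.10 ± 0.403. The list of X-inactivation and Y-linked genes held too few genes for the test, and values of Xist, Eif2s3y, Kdm5d and Uty stand above.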

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

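The tests on the title-number sets, the sex-biased genes, Ighm and the split counts of probe sets were chosen after the result was seen; the count of lists over other splits was not.

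The difference between LIGHT Tg and WT was not alike in the title-number sets for 15 probe sets at 5% FDR (limma interaction term, 2 residual degrees of freedom, smallest adjusted p = 7.82e-05), and 2474 had an unadjusted p below 0.05. The pair holds 1 array of each genotype, so the spread comes from the other 4 arrays, the lone arrays are assumed to vary like them, and the term does not part genotype from a difference between 2 single mice. Of the 15, 10 had 1 gene symbol. Sult3a1, a female-biased sulfotransferase gene, differed by 8.26 on the log2 scale in the pair titled 77 and 78 and by 1.62 in the other arrays, Abcd2 by 4.04 and -0.19 at 1 probe set, and the male-biased Mup3 by -2.02 and -0.02. The brighter probe set of Abcd2, which stands for it in the female-biased list, had 0.90 and -0.31 and is not among the 15. Abcd2 and Mup3 were chosen after their values were seen, as was Sult3a1. The female-biased list had an interaction adjusted p of 3.27e-15 and the male-biased list 9.62e-10 with camera at the preset correlation, where 7 of 24 lists passed. With an estimated correlation 0 passed, with unadjusted p = 0.0302 for the female-biased and 0.0528 for the male-biased list.

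In the pair, LIGHT Tg 1 lacked the sex-biased pattern of WT 1. The mean log2 signal of 13 female-biased genes was 7.06 in WT 1 and 10.5 in LIGHT Tg 1, and between 10.8 and 11.1 in the other 4 arrays; that of 9 male-biased genes was 12.5 in WT 1, 9.68 in LIGHT Tg 1 and between 9.38 and 9.97 elsewhere. A female sample in LIGHT Tg 1, or 10% or more of RNA from one, is argued against by its Xist signals, which were 0.0809%, 2.67% and 5.09% of the lowest of the arrays titled 30 to 35 at the 3 probe sets. A smaller admixture and a fault of a single array were not tested. A difference between 2 single mice that has nothing to do with genotype cannot be told apart from one of genotype, since the pair holds 1 array of each (adjusted p = 0.634 with an estimated correlation). A reduced sexual pattern in male LIGHT Tg livers is a hypothesis that 1 array of each genotype may raise and cannot settle.

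The arrays titled 77 and 78 stand apart from the other 4. Sex alone is argued against as the whole difference, since the lowest 18S signal of the arrays titled 30 to 35 was 71.7 times the highest of the pair at the 5' probe set, 107 times at the middle one and 8.12 times at the 3' one. Labelling or array processing alone is argued against too, since Xist was higher in the arrays titled 30 to 35, 18 times at the brightest of its 3 probe sets, while Eif2s3y had 1037 and 1272 in the pair and lay below 167.4, the signal of the filter, elsewhere. The BioB 3' control probe set had signals of 24.96 on WT 1 and 21.44 on LIGHT Tg 1, against 110.4 to 131.2 on the other 4 arrays. The Xist and Eif2s3y signals show a male pattern in the pair and a female pattern in the other 4 arrays. That difference in sex together with one in RNA processing, labelling or array processing may account for the values above. Which of these processing steps differed cannot be told apart here. How many of the 6163 probe sets each accounts for stays open.

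Ighm rose in LIGHT Tg at 2 of 6 probe sets. More B cells or plasma cells in the livers may account for it and stay open. The other 5 measured markers of that list had a median log2 change of 0.136 (SD 0.447), but background at these probe sets was not measured, so a rise of low transcripts can be hidden. Jchain, the immunoglobulin joining chain gene, had 0.94 (adjusted p = 0.335), with 0.08 in the pair and 1.38 in the arrays titled 30 to 35. Another transcript read by those 2 probe sets was not tested.

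Over the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probe sets past 5% FDR as the genotypes, the genotype split itself with 264. The highest other split gave 0. Each other split mixes the genotypes, so a genotype difference widens its spread and makes a low count likely. At unadjusted p below 0.05 the genotype split had 2473 probe sets, and WT 1, LIGHT Tg 1 and LIGHT Tg 3 against the rest had 2747. That split has both arrays of the title pair on one side. Splits of that kind had between 1981 and 2747, so they also hold the difference between the title-number sets. The remaining splits that mix the genotypes had between 87 and 254. For lists, 7 of the 10 splits, the genotype split included, gave as many as its 6, and the highest other gave 15. With 10 splits no share under 0.05 is possible. Splits with both arrays of the title pair on one side gave 2 to 7 lists.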

How the results depend on the processing

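Use of the arrays titled 30 to 35 alone was chosen after seeing the data. The 264 probe sets became 148 without the variance trend, 1992 with array weights, 1457 with the title-number block, 956 in the arrays titled 30 to 35 and between 43 and 306 with 1 array left out; 206 to 284 passed under the other settings. The 6 lists became 0 with an estimated correlation and 2 with fry, between 4 and 10 with 1 array left out, and 4 to 7 elsewhere; the cause of these changes was not tested. The brighter Tnfsf14 probe set had a positive log2 difference in every setting run, between 0.59 and 2.13, and passed in none; the other, with -0.55, was not run in these settings. Of 122 named genes, 46 passed the threshold and none of these changed sign; 15 passed with any 1 array left out. Quantile normalization ended 4 calls, no filter 13 and no trend 16, and the block added 23. Signs turned only in genes and lists that did not pass: with quantile normalization Dcn 0.034 and Apoa1 0.076; with array weights Mrc1 -0.051, Colec11 -0.018, Alas2 0.17, Apoa1 0.0056, Ttr 0.060, Abcd2 -0.50 and the cell cycle list -0.31; with the mean of all probe sets Zap70 0.62, Ttr 0.0022 and the MHC class II list -0.10; with the stricter filter the MHC class II list -0.088; in the arrays titled 30 to 35 Mrc1 -0.073, Alas2 0.29, Apoa1 0.018, Ttr 0.044, Hamp -0.0062, Abcd2 -0.31 and the cell cycle list -0.13. The direction of a list is that of its test. With 1 array left out Abcd2 ranged from -0.44 to 0.43, Alas2 -0.95 to 0.14, Apoa1 -0.052 to 0.070, Colec11 -0.10 to 0.25, Csf1r -0.19 to 0.10, Dcn -0.17 to 0.12, Epcam -1.60 to 0.57, Fabp4 -0.14 to 0.54, Hamp -0.049 to 0.66, Mrc1 -0.018 to 0.22, S100a8 -0.70 to 0.83, Slc4a1 -0.23 to 0.33, Ttr -0.080 to 0.083 and Zap70 -0.34 to 0.21. List medians ranged from -0.19 to 0.15 for Kupffer cell, -0.25 to 0.075 for MHC class II, -0.21 to 0.23 for cell cycle, -0.11 to 0.18 for interferon and -0.70 to 0.18 for neutrophil genes. The cause of these turns was not tested. With 1 array left out, and no block, the title-number sets were unequal between the genotypes. No paired analysis was possible because the replicate numbers only name the samples. Signal over background could not be given for any probe set, as detection calls were not used here; the brighter Tnfsf14 probe set lay at the 8.88th percentile of level.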

Other observations

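The test in this part was chosen after the result was seen, and so were its genes. Bmp7, a bone morphogenetic protein (BMP) gene, and Id1, Id2 and Smad6, known as targets of BMP signalling, were higher in LIGHT Tg and were picked for that. Bmp7 rose by 2.70 ± 0.457 on the log2 scale (adjusted p = 0.0470), Id1 by 1.91 ± 0.220, Id2 by 1.60 ± 0.224 and Smad6, an inhibitory Smad gene, by 2.00 ± 0.219 (SE, n = 3 per group). All 4 passed with the title-number block, and each lost the call with at least 1 array left out, with adjusted p up to 0.199 for Bmp7, 0.0870 for Id1, 0.120 for Id2 and 0.0870 for Smad6.

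The hypothesis that BMP targets rise in general was tested on the other targets measured past the filter, Id3, Id4, Smad7, Bambi and Hamp. Id3 had 1.16 ± 0.249 (adjusted p = 0.0978, and 0.0216 with the block), and the other 4 lay between -0.17 and 0.38. The median of the 5 was 0.163 (SD 0.546), below 0.956, which is 0.5 times the rise of Id1, by more than that spread. As measured, Id4, Smad7, Bambi and Hamp did not rise as Id1 did, and Id1 was itself picked for its rise. Background at these probe sets was not measured, so a rise of low transcripts can be hidden. A general rise of these targets and one limited to Id1, Id2, Id3 and Smad6 both stay open.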
